A study of Mus musculus with 10 samples.

How the data were processed

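Total RNA from sorted mouse mammary epithelial cells was measured on 10 Affymetrix arrays, 1 array per sample. The deposited table holds 1 intensity per probe set and array on a linear scale. The submitters' processing notes name Affymetrix Expression Console 1.1 and PLIER 2.0 (an algorithm that summarises the probes of a probe set), without saying which step each carried out. Whether the arrays were normalized to each other is not given in the sources used here. The 10 medians lay between 205 and 228 and the upper quartiles differed between arrays, so the columns had not been forced to 1 distribution. The table holds 28815 probe sets, with intensities from 0.000261 to 81263.63. It carries no detection calls or background estimates that were used here, so a low value shows a low signal and not that a gene was silent. No scan date or batch label was used, so batches could not be examined.

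Probe sets were named through the platform annotation supplied with the table. 21780 probe sets had exactly 1 gene symbol, 1605 had several and 5430 had none. Of the single symbols, 21689 matched the current gene table and 91 kept the symbol of the annotation. Probe sets with several symbols or none were not named and did not enter the main tests. No genome build was used, so no coordinates are given.

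Values were taken as log2(intensity + 16), and every log2 difference and fold is on that scale, which understates the change of dim genes. The 25% of probe sets with the lowest mean over all arrays were dropped, which removed those with a mean log2 value under 6.74 and kept 21611. Each gene symbol was represented by its brightest probe set, a choice that mattered for 820 genes with more than 1. This left 15815 genes. A linear model with 3 group means was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which leaves 7 residual degrees of freedom and lets the groups share 1 estimate of the spread. The 3 comparisons were SSKO basal against control basal, control luminal against control basal, and SSKO basal against control luminal. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Spearman correlations between arrays and a principal component analysis described the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

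Before the data were examined, 20 gene lists were written from general knowledge. They covered basal and myoepithelial, mature luminal, luminal progenitor, and milk and alveolar markers; Wnt targets, beta-catenin co-factors, the Notch pathway, H3K4 methylation, the cell cycle, basement membrane and hemidesmosome, lipid and sterol synthesis, immediate early and dissociation stress, and the interferon response. The last 7 lists held markers of other cell types, namely fibroblasts, pericytes, adipocytes, immune cells, endothelial cells, erythroid cells and skeletal muscle. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 20 lists. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the members move on balance in 1 direction and makes no comparison with other genes. A luminal minus basal marker score was computed per array and compared between the 7 basal arrays by an exact two-sided permutation test over all 35 splits into 4 and 3. Its luminal part was the mean over the mature luminal, luminal progenitor, and milk and alveolar members together. Its basal part was the mean over the basal and myoepithelial members. The correlation of the SSKO and luminal contrasts across genes was set beside 100 simulated pairs of unchanged groups against the same controls, and beside the 6 ordered splits of the 4 control arrays.

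Genes were named by a rule written before the data were examined. It took Pygo2, then the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap. Places left open went to the genes of smallest p with non-overlapping groups, given as values only. From each gene list it took up to 4 called members, or the 2 of smallest p where none was called, plus the 2 brightest members of the lists of other cell types. Predicted gene models, olfactory and vomeronasal receptors and small RNA genes could be counted without being named. A gene named outside this rule is said to have been chosen after its values were seen.

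The steps were tested on simulated data in which 50 genes at each of 4 sizes were changed by known amounts. In the SSKO comparison, 12% of genes changed by a log2 value of 0.5 were recovered, 76% at 1 and 100% at 2 and at 3. In the luminal comparison the shares were 10%, 72%, 92% and 100%. The SSKO simulation called 148 genes, against 6 in the real comparison, so the adjusted threshold was easier to pass there. The simulated noise was also drawn for each gene on its own. These shares may therefore overstate the recovery in the real SSKO comparison. The precision is limited by the number of arrays.

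Alternatives were quantile normalization, centring of each array, pseudocounts of 1 and 64, other filters on dim probe sets, the mean of a gene's probe sets, all probe sets, a fit to the compared groups alone, another variance model, array weights, the replicate number as a block, other thresholds and list tests, and leaving out each array in turn. A fit with an endothelial score as a covariate, and a fit without the 3 basal arrays brightest for endothelial markers, were added after the data had been seen.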

Results

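Gene expression was profiled in epithelial cells sorted from the mammary glands of virgin female littermates, control or Pygo2 SSKO, aged 8 to 12 weeks. Glands were digested with collagenase, and cells that carried CD31, CD45 or TER119 (markers of endothelial, blood and erythroid cells) were gated out. The remaining cells were sorted into a CD29-high, CD24-positive population that contains the mammary stem cells and the basal cells, called basal here, and a CD29-low, CD24-positive, CD61-negative population of mature luminal cells. There were 4 control basal, 3 SSKO basal and 3 control luminal arrays. Pygo2 encodes a PHD-finger protein that binds methylated histone H3 and takes part in beta-catenin-dependent transcription. The labels do not spell out SSKO, and the series title calls the mutant cells Pygo2-null. The labels call the samples biological replicates without saying how many animals each was made from, so the p-values measure the spread between these samples. No SSKO luminal arrays were analysed here.

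The luminal arrays stood apart from all basal arrays. The first principal component held 77.7% of the variance and separated luminal from basal arrays. Spearman correlations across the genes tested were 0.932 to 0.963 between control basal arrays, 0.964 to 0.971 between SSKO basal arrays and 0.957 to 0.975 between luminal arrays. SSKO and control basal arrays correlated as closely with each other, at 0.940 to 0.980, whereas control luminal and control basal arrays correlated at 0.702 to 0.809. The value of 0.980 belonged to control array 1 and SSKO array 1, above every pair within a basal group. The main fit does not model such pairs.

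The comparison of SSKO with control basal cells asked how loss of Pygo2 alters expression in the stem cell and basal compartment. The targeted gene was lower in every SSKO array. Pygo2 had log2 values of 8.30, 9.09, 8.11 and 8.91 in control basal arrays 1 to 4, and of 6.99, 5.94 and 5.86 in SSKO basal arrays 1 to 3. Its mean was 8.60 ± 0.47 (SD, n = 4) in control and 6.26 ± 0.63 (SD, n = 3) in SSKO basal cells, a difference of -2.34 (SE 0.32, limma adjusted p = 0.0441). The SSKO mean lay under 6.74, the level below which probe sets were dropped as dim, so the full size of the fall and any remaining transcript are not known. Whether probe set 10493530 lies in the deleted part of Pygo2 was not determined here, and a probe outside it would check nothing. The call of Pygo2 ended when control array 1, 2 or 4 or SSKO array 2 or 3 was left out, with adjusted p = 0.0783, 0.146, 0.115, 0.0614 and 0.363, and after quantile normalization (0.0735), in a fit to the compared groups alone (0.118), with the replicate number as a block (0.176) and with the endothelial score as a covariate (0.0891), while the difference lay between -2.14 and -2.44 in the 5 fits without 1 array that lost the call.

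Besides Pygo2, 5 genes were called in SSKO basal cells, and all 5 rose. AW112010, a gene induced by interferon in immune cells, rose by 2.51 (SE 0.24, adjusted p = 0.00447) from 7.60 ± 0.49 to 10.11 ± 0.27, or 5.68-fold. Fgb, the fibrinogen beta chain, rose by 2.31 (SE 0.32, adjusted p = 0.0443) and Itih2, a heavy chain of the inter-alpha-trypsin inhibitor family, by 2.22 (SE 0.20, adjusted p = 0.00431). Cited1, a transcriptional co-regulator found in hormone-responsive luminal cells, rose by 1.56 (SE 0.18) and the tetraspanin Tspan1 by 1.50 (SE 0.17), each with an adjusted p of 0.0103. The control mean of Tspan1, 5.93, lay under 6.74, so the full size of its rise is not known. In each of these genes the 3 SSKO arrays lay above the 4 control arrays and below the 3 luminal arrays. Luminal means were 12.53 for AW112010, 12.70 for Fgb, 11.36 for Itih2, 12.29 for Cited1 and 11.30 for Tspan1. All 5 were also among the 3887 genes called higher in control luminal cells, where 1.23 would be expected of independent lists, although both comparisons share their control arrays. Probe sets were 10466127 for AW112010, 10498981 for Fgb, 10480003 for Itih2, 10606083 for Cited1 and 10515282 for Tspan1.

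**Figure D1:**
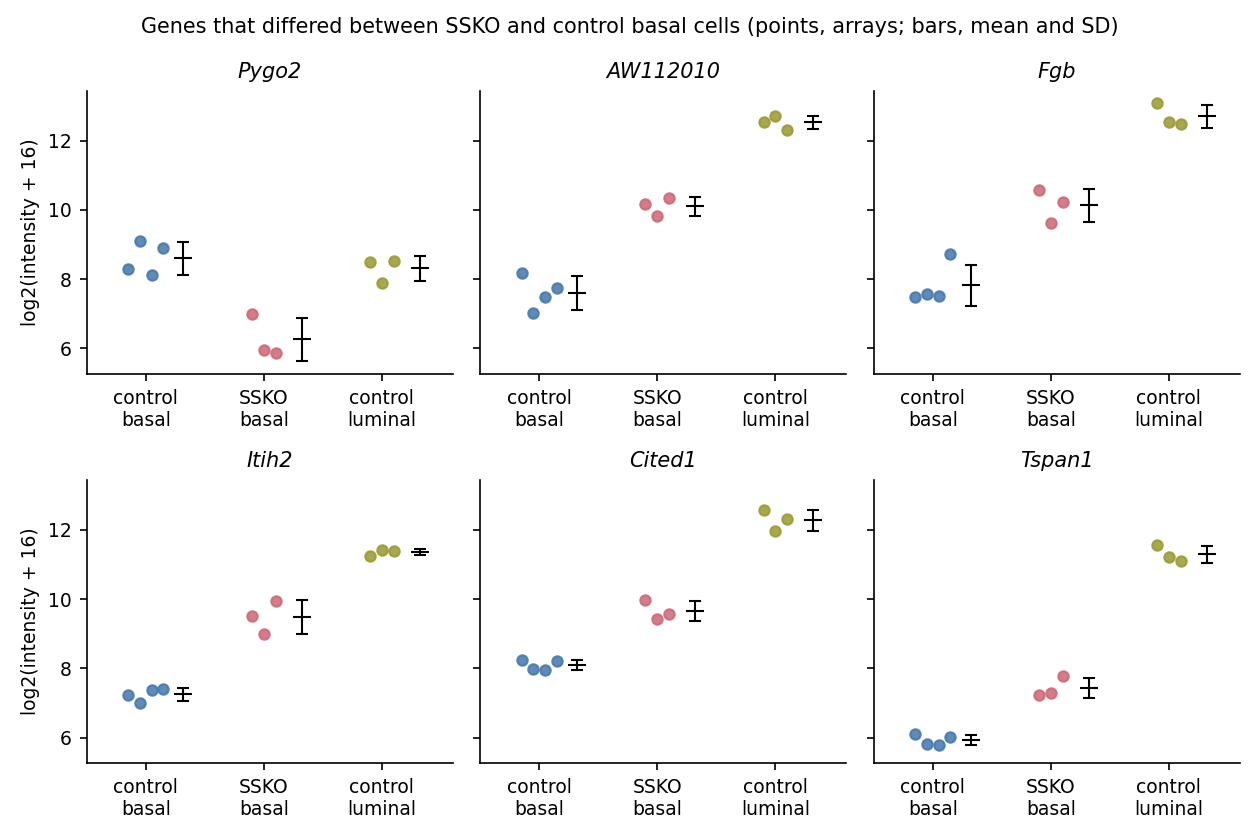
The 6 genes called between SSKO and control basal cells, as log2(intensity + 16) in each array, with the 3 groups on the horizontal axis. Points are arrays and bars show the mean and SD (n = 4, 3 and 3). Pygo2 lies at 5.86 to 6.99 in SSKO basal arrays, and the other 5 genes lie between the control basal and control luminal levels there.

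The count of 6 called genes out of 15815 was small, and 479 genes (3.03%) had an unadjusted p under 0.05 where 790.75 would be expected by chance. Groups did not overlap for 706 genes (4.46%), and chance gives 5.71%. The count was 1 without SSKO array 3, 2 without control array 2 and 27, all higher, without SSKO array 2. It was 3, with 3 higher and 0 lower, after quantile normalization, and limma called 0 genes (214 at an unadjusted p under 0.05) without control array 1 and SSKO arrays 1 and 3, the 3 basal arrays brightest for endothelial markers, a fit added after the data had been seen that leaves 1 SSKO array, assumed to vary like the other groups. In that fit the differences stayed large, at -2.76 for Pygo2, 2.40 for AW112010, 1.72 for Itih2, 1.68 for Fgb, 1.42 for Tspan1 and 1.39 for Cited1. Of the genes that rose, Itih2 stayed called without any 1 array. AW112010 lost its call without SSKO array 3 (adjusted p = 0.0535), Cited1 and Tspan1 without control array 2 (both 0.0564) or SSKO array 3 (both 0.0662), and Fgb without control array 1, 2 or 3 (0.152, 0.173 and 0.160) or SSKO array 1 or 3 (0.302 and 0.363). The Tspan1 call also ended with the replicate number as a block (0.0616) and after quantile normalization (0.0555). The Fgb call ended after quantile normalization (0.0579), with the variance model that allows a trend (0.0573), with array weights (0.0813), in a fit to the compared groups alone (0.133) and with the endothelial score as a covariate (0.136).

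Further genes of small p did not pass and are given as values. On the higher side were R3hdml (log2 difference 1.62, adjusted p = 0.0551), Krt19, a simple epithelial keratin (1.44, 0.0934), the cation channel Trpc6 (1.07, 0.0934), Wfdc2 (1.11, 0.105) and Mlph, a melanosome transport protein (0.68, 0.105). On the lower side were the tetraspanin Tspan8 (-1.63, adjusted p = 0.181), the carbonic anhydrase-related Car8 (-0.75, 0.25), Lrrtm1 (-0.88, 0.977) and Pcdh18 (-0.62, 0.977). Without SSKO array 2, R3hdml, Krt19 and Trpc6 passed (adjusted p = 0.00698, 0.0427 and 0.0280). R3hdml also passed after centring of the arrays (0.0425), with a pseudocount of 1 (0.0468) and with the variance model that allows a trend (0.0454). Krt19 also passed without control array 4 (0.0379) and with the replicate number as a block (0.031), and Tspan8 without SSKO array 1 (0.0243) and with the endothelial covariate (0.0448).

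No difference was detected in basal identity genes, although small changes would mostly be missed with these arrays. None of the 20 measured members of the basal and myoepithelial list passed, and the median log2 difference was 0.02 (camera adjusted p = 0.897). The contractile genes Actg2 and Tagln, which had the smallest p, differed by 0.29 and 0.18 with adjusted p near 1. The mature luminal list, made of hormone receptor, luminal keratin and claudin genes, was shifted upward, with a median of 0.13 over 18 members (camera adjusted p = 1.08e-07). With an estimated correlation the adjusted p was 0.0630, and with fry it was 0.0565. Its mean level per array overlapped between the groups, at 0.13 in control array 4 and 0.09 in SSKO array 2 relative to the basal arrays. Cited1 alone rose over all genes tested and the other 17 members did not pass. Adjusted over the list alone, 5 members rose, namely Cited1, Krt19, the pioneer factor Foxa1 (1.11, SE 0.18) and the tight junction genes Cldn4 (0.98, SE 0.27) and Cldn3 (0.59, SE 0.13), the last 3 named after their values had been seen. The hormone receptors Esr1 (-0.34, SE 0.33) and Pgr (0.26, SE 0.20), also chosen after their values were seen, did not pass. The luminal progenitor list did not pass (camera adjusted p = 0.15), and its median of 0.01 and its camera direction, downward, differed in sign. Adjusted over the list alone, Tspan8 fell, with a difference of -1.63 whose full size is not known since its SSKO mean of 6.23 lay under 6.74, and Elf5, an alveolar transcription factor, had a difference of -0.46. The milk and alveolar list was shifted downward (median -0.22 over 19 members, camera adjusted p = 0.0201), with adjusted p = 0.476 with an estimated correlation. None of its members passed over all genes. Adjusted over the list alone the water channel Aqp5 rose by 0.78, and the casein Csn3 had a difference of -0.79.

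The luminal minus basal marker score was -1.71 ± 0.23 (SD, n = 4) in control basal, -1.73 ± 0.33 (SD, n = 3) in SSKO basal and 4.01 ± 0.87 (SD, n = 3) in control luminal arrays. The difference between SSKO and control basal arrays was -0.03 (two-sided exact permutation p = 0.886, 35 splits, smallest possible p 0.0286), smaller than the spread within either group. The 3 lists in the luminal part of the score went different ways. Mean log2 differences were 0.33 for mature luminal, -0.11 for luminal progenitor and -0.25 for milk and alveolar genes. The small score difference therefore does not show that mature luminal genes were unchanged. Glycam1 is a member of the milk and alveolar list. It was 14.16 in control array 1, 16.18 in SSKO array 1 and 15.25 in SSKO array 3, against 7.45 to 7.99 in the other basal arrays. It thus raised the milk and alveolar mean difference and the luminal part of the score in SSKO relative to control arrays.

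Of the pathway lists tied to Pygo2, those for Wnt targets, beta-catenin co-factors and Notch did not pass. The 20 measured Wnt targets had a median of 0.05 (camera adjusted p = 0.346), with Ccnd1, a G1 cyclin, at 0.89 and Procr at 0.81, neither past the test. The 15 beta-catenin co-factors had a median of -0.01 (0.779), with Chd8 at -0.19 and Ldb1 at 0.10. The 22 Notch genes had a median of 0.04 (0.133), and the receptor Notch3 and the target Hes1 had differences of 0.55 (SE 0.17) and 0.51 (SE 0.21) with adjusted p near 1. The 15 H3K4 methylation genes, writers and erasers of the mark that Pygo2 binds, were shifted downward with a median of -0.09 (0.0486, and adjusted p = 0.476 with an estimated correlation), with no member past the test and the demethylases Kdm5a at -0.35 and Kdm5b at -0.23. The cell cycle list (31 genes, median -0.12, 0.15), basement membrane and hemidesmosome (13, 0.02, 0.897), lipid and sterol synthesis (16, 0.01, 0.779) and immediate early genes (22, 0.05, 0.293) did not pass. Examples were Mcm4 (-0.20), Lama1 (-0.38), Srebf1 (-0.20) and Klf2 (0.58), none past the test.

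Several lists of other cell types passed, with levels that differed between arrays of the same group. The endothelial list had the largest median shift of the 20 lists, 0.74 over 12 members (camera adjusted p = 2.94e-04, and adjusted p = 0.476 with an estimated correlation), with no member past the test and 11 above 0. The differences of Egfl7, Cdh5 and Eng were 1.13 (SE 0.57), 0.93 (SE 0.64) and 0.58 (SE 0.28), and without SSKO array 2 Egfl7 passed (2.02, adjusted p = 0.0427). Relative to the mean of the basal arrays, the list stood at 0.71 in control array 1, at 1.66 in SSKO array 1 and at 0.65 in SSKO array 3, and at -0.90, -0.43, -0.63 and -1.06 in control arrays 2, 3 and 4 and SSKO array 2. The interferon list had a median of 0.39 over 14 members, 13 of them above 0 (camera adjusted p = 6.14e-04, and 0.476 with an estimated correlation), with Bst2 at 0.40 and Usp18 at 0.58. Small upward shifts were also seen for adipocyte (9 genes, 0.30, camera adjusted p = 6.24e-04), skeletal muscle (10, 0.16, 0.00122) and pericyte markers (9, 0.14, 0.0189), with estimated-correlation adjusted p = 0.0630, 0.476 and 0.190. Examples were Plin1 (0.30), Acta1 (0.58) and Des (0.82), the last of which rose when adjusted over the list alone. Fibroblast markers were shifted downward (12 genes, -0.28, 0.0106, and adjusted p = 0.477 with an estimated correlation), with Fbln1 at -0.62 and Pdgfra at -0.92. Immune (15 genes, 0.07, 0.133) and erythroid markers (2 genes, 0.01, 0.961) did not pass, with Cd74 at 0.88 and Alas2 at 0.02. Altogether 9 of the 20 lists passed with camera, and 0 passed either with an estimated correlation (3 at an unadjusted p under 0.05) or with fry (3).

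Most of these list calls rested on single arrays. The endothelial call ended without SSKO array 1, where the median went from 0.74 to 0.20 (camera adjusted p = 0.903), while the median was 1.55 without SSKO array 2 and 1.12 without control array 1. The interferon median went from 0.39 to 0.20 without control array 2 (0.0594), to 0.15 without SSKO array 3 (0.15) and to 0.14 with the endothelial score as a covariate (0.261), and its call ended in each, while it kept its call at 0.23 without control array 3. The fibroblast median turned from -0.28 to 0.05 without control array 3 (0.810), so its downward direction rested on that array, went to -0.08 without SSKO array 2 (0.507), and was -0.46 without control array 1 and -0.45 without SSKO array 3. The milk and alveolar call ended without control array 1 (median -0.29, 0.158), control array 2 (-0.13, 0.148) or SSKO array 2 (-0.21, 0.436), and the skeletal muscle call without control array 1 (0.11, 0.0539) or SSKO array 2 (0.09, 0.0581), with a median of 0.24 without control array 2 or SSKO array 1. The pericyte call ended without control array 2 (0.24, 0.0503), SSKO array 1 (0.17, 0.259) or SSKO array 3 (0.11, 0.0550), with a median of 0.28 without control array 4, and with the endothelial covariate (0.15, 0.117). The H3K4 methylation median of -0.09 went to -0.07 without control array 2 (0.125), to -0.01 without control array 4 (0.195), to -0.03 without SSKO array 1 (0.338), to -0.04 with the endothelial covariate (0.321) and to -0.01 with the replicate number as a block (0.158), and its call ended in each. That call also ended after quantile normalization (0.262) or centring of the arrays (0.0686), with a stricter filter on dim probe sets (0.117), in a fit to the compared groups alone (0.0732) and with array weights (0.0582). With that stricter filter the adipocyte (0.165) and milk and alveolar calls (0.0969) ended, and with array weights the milk and alveolar (0.0582) and pericyte calls (0.0508). The mature luminal and adipocyte calls held without any 1 array. The mature luminal median of 0.13 was 0.26 without control array 4 and 0.23 without SSKO array 1. It was 0.27 with the replicate number as a block, where the pericyte median was 0.29, and 0.22 with the endothelial covariate. Cell cycle genes passed without control array 2 (median -0.51, 1.23e-06) or SSKO array 3 (-0.24, 0.0214), luminal progenitor genes without control array 4 (-0.24, 0.0216) or SSKO array 1 (-0.16, 0.0229) and with the replicate number as a block (-0.24, 0.00879) or the endothelial covariate (-0.11, 0.0286), immediate early genes without control array 2 (0.0207), lipid and sterol genes without control array 3 (0.0407), Notch genes without SSKO array 2 (0.0284) and immune genes without SSKO array 3 (0.00458).

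**Figure D2:**
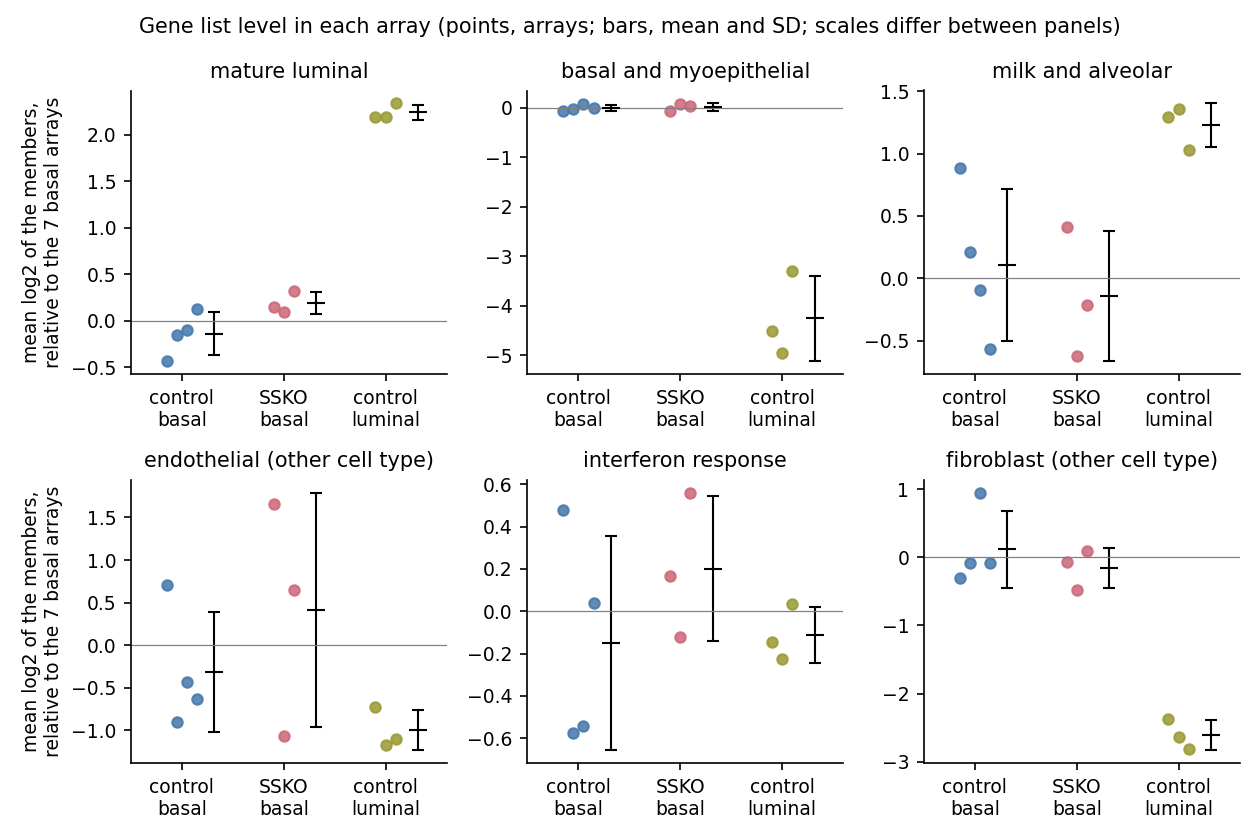
Mean log2 level of 6 gene lists in each array, relative to the mean of the 7 basal arrays, with the 3 groups on the horizontal axis. Points are arrays and bars show the mean and SD, and the vertical scales differ between panels. Each of the 6 lists overlaps between SSKO and control basal arrays, mature luminal included (0.13 in control array 4, 0.09 in SSKO array 2). Among basal arrays, the endothelial list is highest in SSKO arrays 1 and 3 and control array 1.

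The comparison of control luminal with control basal cells described the difference between the normal compartments. It called 7001 of 15815 genes, 3887 higher and 3114 lower in luminal cells, of which 1456 and 1618 differed by over 2-fold. The median difference of all genes was 0.07. At an unadjusted p under 0.05 there were 7930. Genes with large falls were Reln, a secreted glycoprotein (-5.93, SE 0.35), Kcnmb1, a calcium-activated potassium channel subunit (-5.86, SE 0.17), the proteoglycan Fmod (-5.82, SE 0.23), smooth muscle myosin Myh11 (-5.81, SE 0.29), smooth muscle actin Actg2 (-5.79, SE 0.23) and Igfbp3 (-5.66, SE 0.29). Il17b, Mylk, Cacna2d1 and Cnn1 differed by -5.49, -5.47, -5.45 and -5.43. Luminal means of Reln (5.63), Kcnmb1 (5.42), Fmod (5.8), Actg2 (6.22), Il17b (6.71), Mylk (6.26) and Cacna2d1 (5.46) lay under 6.74, so the full sizes of these falls and their order are not known, which holds for every gene whose lower mean lies under that level. Genes with large rises were Aoc1, a diamine oxidase (6.68, SE 1.15), Cyp3a57 (6.57, SE 0.40), Cdcp3 (6.22, SE 0.27), the neurexin Nrxn3 (6.22, SE 0.25), the chemokine Cxcl15 (6.21, SE 0.56), Dkkl1 (5.95, SE 0.21), Ido1, a tryptophan-degrading enzyme (5.92, SE 0.55), Olfm4 (5.90, SE 0.65) and the sodium-iodide symporter Slc5a5 (5.68, SE 0.32). Dpep2 rose by 5.73 in its brightest probe set, whereas its other probe set had a difference of 0.27. Each of these genes had an adjusted p of 6.37e-04 (Aoc1) or less and groups that did not overlap. Pygo2 itself did not pass (-0.29, SE 0.32, adjusted p = 0.515).

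Lineage lists separated the compartments. All 20 measured basal and myoepithelial genes fell (median -4.45, camera adjusted p = 4.86e-15, and adjusted p = 0.169 with an estimated correlation), for example Actg2 by 5.79 and Mylk by 5.47. Of the mature luminal list, 16 of 18 rose and 2 did not pass (median 2.41, 2.50e-09, and adjusted p = 0.0790 with an estimated correlation), among them Foxa1 (5.35), the stem and luminal surface gene Prom1 (5.37), Cited1 (4.19) and Cldn3 (3.43). Of 19 milk and alveolar genes, 9 rose and 10 did not pass (1.19, 0.0154, and adjusted p = 0.331 with an estimated correlation), including Aqp5 (4.80), the milk fat globule gene Btn1a1 (3.55) and the prolactin signal transducers Stat5a (1.75) and Stat5b (1.67). The luminal progenitor list did not pass (0.52, 0.476), and its members split, with Elf5 (2.75) and Kit (3.06) among the 6 that rose and the integrins Itgb3 (-2.47) and Itga2 (-1.65) the 2 that fell. Itgb3 encodes CD61, on which the luminal gate selected.

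Wnt pathway genes were lower in luminal cells. Of the 20 Wnt targets, 15 fell, 1 rose (Ccnd1) and 4 did not pass (median -1.65, camera adjusted p = 2.94e-06, and adjusted p = 0.0790 with an estimated correlation). The listed targets Nkd1, Nkd2, Wif1 and Bambi all fell, with differences of -4.75, -3.70, -4.79 and -2.79. Of 15 beta-catenin co-factors, 6 fell, 2 rose and 7 did not pass (-0.28, 0.0288, and adjusted p = 0.396 with an estimated correlation). Among those that fell were Pygo1, the paralog of Pygo2 (-2.66), the TCF family gene Tcf7l1 (-2.59), Ssbp2 (-1.56) and the co-repressor Tle1 (-1.40). The co-factor call ended without control luminal array 2 (0.0517) or with a stricter filter on dim probe sets (0.054). Notch genes did not pass as a list (-0.36, 0.0713) and went both ways, with 4 rising, such as Notch3 (2.50) and Dtx4 (2.68), and 9 falling, such as the ligands Dll1 (-4.94) and Jag1 (-1.86). They passed without control luminal array 3 (0.0342) and without the filter on dim probe sets (0.0277).

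Of 13 basement membrane and hemidesmosome genes, 10 fell, 2 rose and 1 did not pass (median -3.40, camera adjusted p = 1.28e-05, and adjusted p = 0.275 with an estimated correlation), led by the collagen IV genes Col4a2 (-4.34) and Col4a1 (-3.88) and the laminins Lama1 (-4.69) and Lamb3 (-3.40). Fibroblast-type genes also fell, 11 of 12 with 1 rising (-3.06, 4.79e-06, and adjusted p = 0.275 with an estimated correlation), including Postn (-4.53), Lum (-4.29), Fbln1 (-3.64) and Col1a1 (-3.50). Of 9 pericyte genes, 6 fell and 3 did not pass (-0.99, 0.00286, and adjusted p = 0.0790 with an estimated correlation), including Pdgfrb (-3.16) and Mcam (-2.37). The remaining lists did not pass. They were immune (15 genes, -0.28, 0.0713), endothelial (12, -0.83, 0.283), cell cycle (31, 0.06, 0.716, camera direction downward), H3K4 methylation (15, 0.19, 0.898), lipid and sterol synthesis (16, 0.34, 0.898), immediate early genes (22, 0.15, 0.898), interferon (14, -0.11, 0.898), adipocyte (9, -0.02, 0.898, camera direction upward), erythroid (2, 0.25, 0.716) and skeletal muscle (10, 0.11, 0.898). Of the immune genes 5 fell, led by Cd74 (-2.44), and of the endothelial genes Vwf rose (1.43) and Cldn5 fell (-1.71). The Vwf call ended without control basal array 2 or 4 or control luminal array 1 or 2 (adjusted p = 0.0568, 0.0603, 0.0683 and 0.0739), and the Cldn5 call whichever 1 of the 7 arrays was left out (0.0555 to 0.140). In the cell cycle list Ccne1 (-1.61) and Pcna (-0.86) fell and Aurka (0.53) and Mcm6 (0.87) rose, the Mcm6 call ending without control basal array 2, 3 or 4 or control luminal array 2 or 3 (0.0615 to 0.0912). Of the H3K4 methylation genes Men1 (-0.56) and Wdr5 (-0.50) fell and Kdm5c (0.44) and Setd1b (0.42) rose, the Setd1b call ending without control basal array 1, 2 or 4 or control luminal array 3 (0.0615 to 0.162). The Setd1b call also ended after quantile normalization (0.0882) or centring (0.0732), in a fit to the compared groups alone (0.0780) and with array weights (0.0835). Of the adipocyte genes Lipe (1.62) and Pnpla2 (0.85) rose and Plin4 (-1.17) and Fabp4 (-1.66) fell, the Fabp4 call ending without control basal array 1 or 4 or control luminal array 2 or 3 (0.0567 to 0.103). Both directions were also found among lipid and sterol genes (4 rose, such as Srebf1 by 0.90, and 4 fell, such as Fasn at -0.83), immediate early genes (7 rose, such as Klf6 by 0.75, and 4 fell, such as Egr2 at -3.20) and interferon genes (4 rose, such as Usp18 by 2.30, and 2 fell, such as Ifit2 at -1.46). Alas2 rose by 0.46, and no skeletal muscle gene passed. The immune list passed without control basal array 4 (0.0270) or control luminal array 1 (0.0440), without the filter on dim probe sets (0.0237), in a fit to the compared groups alone (0.0345), and with the replicate number as a block (0.0109), where the milk and alveolar call ended (0.0505). In all, 8 lists passed with camera, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 11 with fry.

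**Figure D3:**
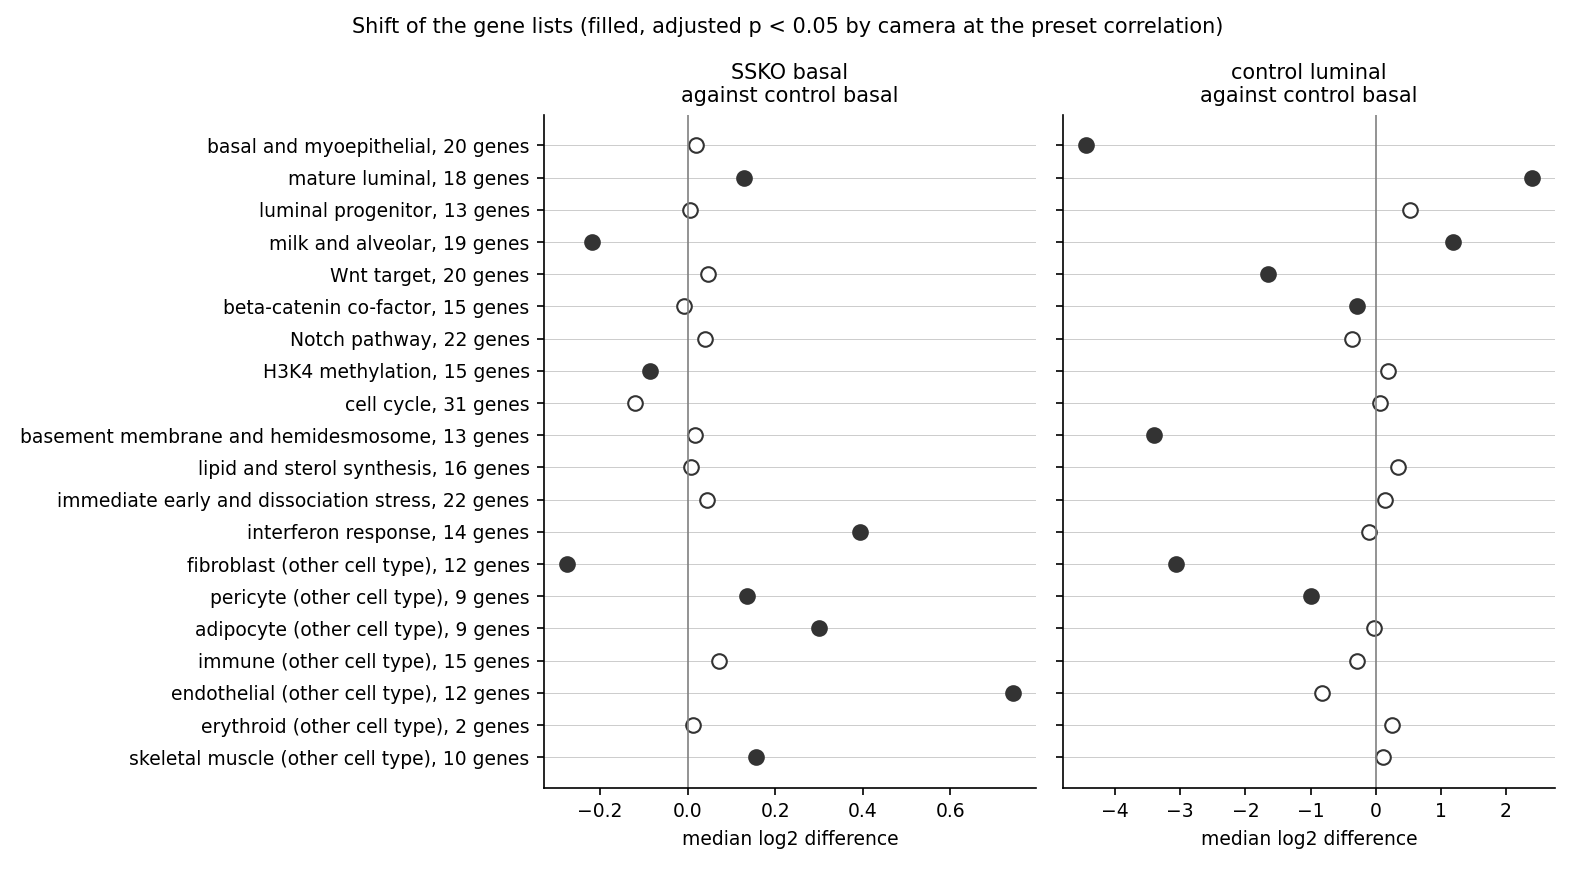
Median log2 difference of the members of the 20 gene lists in SSKO against control basal cells (left) and control luminal against control basal cells (right), with the number of measured genes after each name and different horizontal scales. Filled points passed camera at the preset correlation of 0.01, where 9 lists passed on the left and 8 on the right, and none of these passed with an estimated correlation.

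Whether genes that differ in SSKO basal cells also differ between the compartments was examined across genes, which are not independent replicates. The 2 contrasts correlated with Pearson r = 0.23 over 15815 genes. Unchanged groups simulated against the same controls gave r = 0.43, because the shared controls add the same covariance to smaller differences. The observed covariance was 0.0513 against 0.0224 in the simulation. With the control arrays split between the contrasts, the mean r was 0.09 over 6 splits (-0.01 to 0.17) and the mean covariance 0.0255 (-0.00291 to 0.0456).

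**Figure D4:**
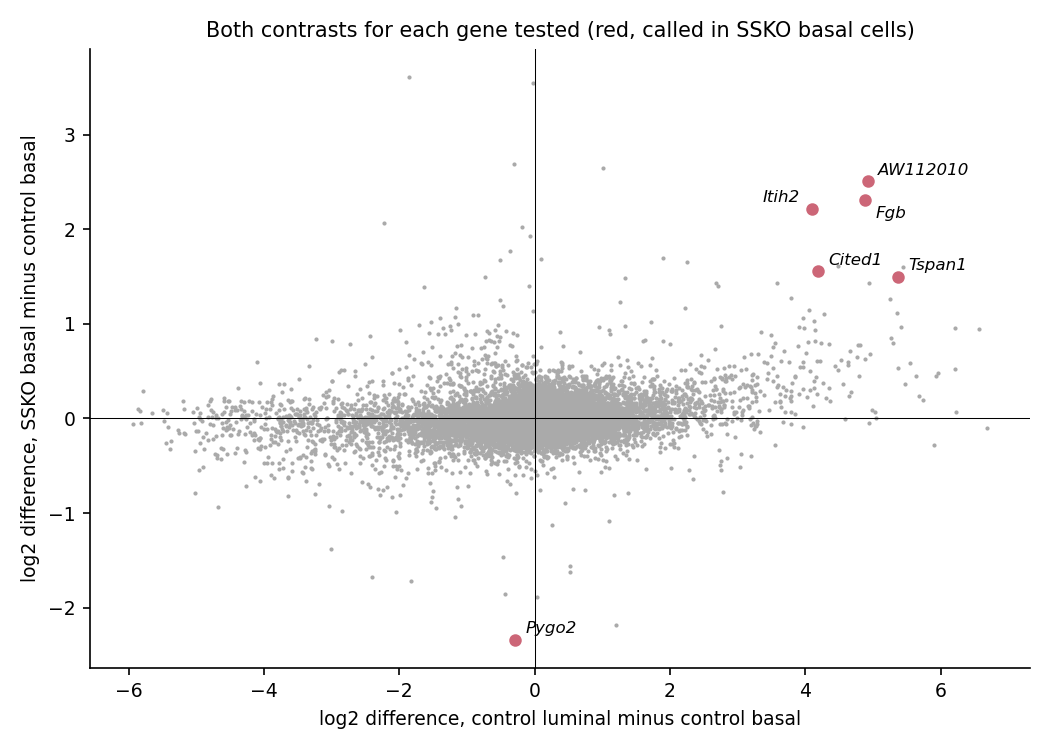
Log2 difference of each of the 15815 genes between SSKO and control basal cells (vertical axis) and between control luminal and control basal cells (horizontal axis). Red points are the 6 called genes; 5 lie at high values on both axes, and Pygo2 lies at -2.34 on the vertical and -0.29 on the horizontal axis.

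SSKO basal cells remained far from luminal cells. Against control luminal arrays, 6682 genes were called, 3000 higher and 3682 lower in SSKO basal cells, and 7706 had an unadjusted p under 0.05. Groups did not overlap for 8610 genes (54.4%), where chance gives 10% for 3 arrays against 3.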

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

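The tests of Tspan1 and of the small rise of the 100 most luminal genes were chosen only after the results had been seen, and so was the setting with the endothelial score as a covariate.

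Among the values of named genes and lists in the 4 control basal arrays, 7 held 1 array far from the other 3. Of 156 groups checked, 7.8 would be picked out by chance, so their number is no more than chance gives. Fgb was 8.71 in control basal array 4 against 7.48 to 7.58 in the others. R3hdml was 6.59 in array 3 against 6.99 to 7.06. Mcm4 was 10.69 in array 1 against 9.95 to 9.98. In array 2, Chd8 was 10.01 against 9.63 to 9.69, Bambi was 10.70 against 10.08 to 10.16, Postn was 12.73 against 13.08 to 13.11, and Klf6 was 12.07 against 12.39 to 12.42.

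The count of called genes was set against other splits of the same arrays. For SSKO against control basal, 2 of 35 splits of the 7 basal arrays, the real one included, called at least as many genes, so chance is not excluded by the count of 6. The highest other split called 71 genes, many times the real count, and put together control array 1 and SSKO arrays 1 and 3, the arrays brightest for endothelial markers, which points to a structure of the samples. For control luminal against control basal, 1 of 35 splits, the real one, reached the count of 7001. That is the smallest share possible (0.0286) and under 0.05, which argues against chance for this count. The highest other called 2213 and set control basal array 1 with the 3 luminal arrays, a division close to the real one. For SSKO basal against control luminal, 1 of 10 splits reached 6682 and the highest other called 0. These 10 splits are too few for a share under 0.05.

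The 5 genes that rose in SSKO basal cells are all luminal genes, and luminal cells carried over in the sort are a candidate source. The called genes imply a median luminal share of 16.5%, 8.70% and 14.5% in SSKO arrays 1, 2 and 3. The 100 most luminal genes imply a median of at most 2.72%, with upper quartiles of 4.46%, 1.58% and 5.45%. AW112010, Cited1, Fgb and Itih2 exceed these quartiles in each array. The called genes were picked for their rise in these same arrays and the 100 were not, so higher shares were partly fixed by that choice. The comparison shows only that these 4 genes rose more than most of the 100, and does not exclude luminal cells as their source. Endothelial cells were argued against as the whole cause, since 94.7% of the median rise of the 5 genes stayed with the endothelial score as a covariate. Fgb lost its call there (from 2.31, SE 0.32, to 2.17, SE 0.34, adjusted p = 0.136), with a slightly smaller rise, a larger SE and a residual degree of freedom taken up by the covariate. Tspan1 implies a share of 3.55% in SSKO array 1, inside the quartiles of the 100 genes there. It implies 3.85% and 6.37% in SSKO arrays 2 and 3, above the upper quartiles of 1.58% and 5.45%. The 100 most luminal genes imply a median of at least 0.745% in each SSKO array against at most 0.424% in control arrays. For Tspan1 and for this small rise, luminal cells and a shift in the mutant cells cannot be told apart, because the shares implied by single genes spread widely. The loss of Pygo2 remains an untested biological explanation for the called genes.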

How the results depend on the processing

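The 2 settings on endothelial markers were added after the data had been seen. The number of genes called between SSKO and control basal cells was 6, and stayed within 1.5 times of that except where named. It was 479 at an unadjusted p under 0.05, 3 after quantile normalization, 0 (limma, 214 at an unadjusted p under 0.05) without the 3 arrays brightest for endothelial markers, and 1 to 27 when single arrays were left out. The number of lists called there was 0 with an estimated correlation and 0 with fry against 9, with 3 and 3 at an unadjusted p under 0.05, and 7 to 9 when single arrays were left out. For luminal against basal cells it was 0 with an estimated correlation against 8, with 4 at an unadjusted p under 0.05, and 7 to 9 when single arrays were left out. The correlation of contrasts was 0.0916 with split controls and 0.19 to 0.28 when single arrays were left out, with a jackknife SE of 0.078. Counts of called genes ranged from 5983 to 7023 for luminal against basal and from 5631 to 6328 for SSKO basal against luminal cells when single arrays were left out, and the marker score difference from -0.20 to 0.14, where too few splits remain for a p under 0.05. The median of the endothelial list reversed to -0.00998 with the endothelial score as a covariate, where the list's own genes are fitted away and the calls of Pygo2, Fgb and the interferon, pericyte and H3K4 methylation lists also ended while Tspan8 and the luminal progenitor and cell cycle lists passed, and to -0.50 (adjusted p = 2.97e-07) without the 3 arrays. Without them the lipid and sterol list stood at 0.32 (0.00703) and the pericyte list at -0.00853 (0.938), the fibroblast list went from -0.28 to -0.84 (4.56e-09), luminal progenitor genes (-0.14, 0.0045) and Wnt targets (0.15, 0.0203) passed, the interferon, adipocyte and H3K4 methylation calls ended, and the cause was not tested. Apart from leaving out arrays, calls of the 6 genes of the SSKO comparison ended 11 times and calls of its 9 lists 31 times, not counting reversals. No list or gene named by the rule reversed in the luminal comparison. With the replicate number as a block, Pygo2 (adjusted p = 0.176), Tspan1 (0.0616) and H3K4 methylation (0.158) lost their calls, and Krt19 (0.031) and luminal progenitor genes (0.00879) gained them. In the luminal comparison with that block, milk and alveolar genes (0.0505), Setd1b (0.0684) and Mcm6 (0.0672) lost their calls and immune genes gained a call (0.0109). In that fit 5 genes were called in SSKO basal cells, 6899 in luminal cells and 6836 between SSKO basal and luminal cells, 9 and 8 lists passed, and the score difference was -0.09 (exact sign-flip p = 1). Deviations of SSKO and control basal arrays of the same number correlated at 0.63, 0.46 and 0.05, and SSKO array 3 correlated best with control array 4 (0.43), so not every array went best with its own number. The block covers only the pairing by number, and other pairings were not tested. The deposited values gave no background, so signal over background could not be judged.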

Other observations

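The fibroblast, milk and endothelial tests below were chosen only after the results had been seen.

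The genes of the sorting antigens, chosen after their values were seen, differed between the compartments. Itgb1 (CD29) was 12.41 ± 0.11 (SD, n = 4) in control basal and 11.63 ± 0.08 (SD, n = 3) in luminal cells, and fell by 0.78 (SE 0.12, adjusted p = 3.73e-04). Cd24a rose by 1.41 (SE 0.13, adjusted p = 4.42e-06). Between SSKO and control basal cells their differences were 0.02 and 0.20, neither past the test. Ptprc (CD45) lay between 6.66 and 7.02 in all 10 arrays, near the level at which probe sets were dropped, whereas Pecam1 (CD31) ranged from 8.31 to 11.31 over the basal arrays.

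The casein Csn2 and proliferation genes varied widely between arrays of 1 group. Csn2 was 11.58, 10.18, 8.78 and 6.04 in control basal arrays 1 to 4, 9.26, 6.40 and 6.11 in SSKO basal arrays 1 to 3, and 10.42, 10.23 and 6.90 in luminal arrays 1 to 3. The proliferation gene Mki67 was 6.55 in control basal array 2 against 9.75 to 9.98 in the other control basal arrays. It was 8.27, 8.43 and 9.47 in SSKO basal arrays 1 to 3, and 7.19, 10.39 and 9.30 in luminal arrays 1 to 3. Top2a was 6.21 in control basal array 2 and 8.85 to 9.71 in the other control basal arrays. In SSKO basal arrays 1 to 3 Top2a was 8.10, 8.06 and 8.89. These genes were chosen after their values were seen.

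Glycam1, which encodes a mucin-like glycoprotein of milk and of high endothelial venules, was 14.16 in control basal array 1, 16.18 in SSKO array 1 and 15.25 in SSKO array 3, against 7.45 to 7.99 in the other 4 basal arrays. Milk gene expression was argued against as the source in all 3 arrays by the caseins, of which 0 of 4 had the same 3 highest basal arrays. In SSKO array 3 all 4 lay below the median of the basal arrays, with Csn1s1 at 5.34 and Csn2 at 6.11. Of the 18 other milk and alveolar genes 0 had the same 3 highest arrays, but chance gives only 0.51, so that count alone decides nothing. Endothelial cells carried over in the sort cannot be told apart from other sources. Of 12 endothelial genes 11 had the same 3 highest arrays, against 3.47% of all other tested genes, with Cdh5 at 11.03, 11.88 and 11.69 there and at 8.90 to 10.01 in the other 4. Pecam1, which encodes CD31, was among the 11, at 10.34, 11.31 and 10.41 there and at 8.31 to 9.27 in the other 4. The gate against CD31 therefore cannot be taken to have left no endothelial cells in these arrays. The count does not settle the source, because the endothelial levels had been seen before it and these genes go together. For high endothelial venules, 0 of 4 measured markers of 7 shared the 3 arrays. By the prediction written beforehand, this would have excluded them. They were left open because only 2 of the 4 lay clearly above the filter on dim probe sets, a condition that was not part of that prediction. These 2 were low in SSKO array 3, where Ackr1 was 6.81, the lowest of the basal arrays, and Gcnt1 was 7.25. In SSKO array 1 they were 10.53 and 8.30, and in control array 1 they were 9.58 and 8.39. No biological explanation was tested, since the 3 arrays come from both groups.

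Control luminal array 3 held more basal transcript than the other luminal arrays. Krt14 was 11.86 there against 8.82 and 7.78, Krt5 was 11.68 against 9.06 and 7.70, and the basal list stood at -3.29 against -4.52 and -4.95 relative to basal arrays. Fibroblasts were argued against, since 2 of 12 fibroblast genes lay above both other luminal arrays. Basal cells in that sort cannot be told apart from other sources, because 84% of the 100 most basal genes lay above both other arrays, under the 90% set beforehand, while 34.8% of all genes did. The basal share implied by the 100 genes had a median of 2.29% with quartiles of 0.876% and 6.45%. Krt14 and Krt5 lay at 13.18 to 13.43 and at 13.20 to 13.55 in control basal arrays. Their levels in luminal array 3 stand for a much larger share than that median, so they are not typical of the basal genes. No biological explanation was tested.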
